A study of Solanum lycopersicum
Meloidogyne incognita with 34 samples.

How the data were processed

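Whole roots of tomato were sequenced as polyA RNA, with and without inoculation by 1500 second-stage juveniles (J2) of Meloidogyne incognita per plant. Seedlings were 5 weeks old. The groups were Pusa Ruby (PR) at day 0 and infected and uninfected at stages 1 to 5, and M36 infected and uninfected at stages 1 and 2. Each stage pooled roots of 3 consecutive sampling days, as the labels give them. The series lists 34 samples, and the tables used hold columns for 30 of them. The other 4, M36 and MM (the parent of the transgenic line) at day 0, were not analysed here.

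The authors gave raw counts per gene, in separate tables for tomato and for nematode genes and for PR and M36. The values are whole numbers with a different total in each library. Their processing notes name CASAVA 1.8, FastQC, cutadapt, TopHat2 2.0.14 and HTSeq; the role of each and the genome build are not given in the sources used here. The labels state that replicate 1 of both infected M36 groups was downsampled because the corresponding uninfected sample was not sequenced paired-end for any replicate. They call some replicates technical, so the p-values may cover technical spread alone. The tomato tables list 34725 genes, zeros included. The lowest row total in either nematode table was 11, so genes with fewer counts than that are not listed. The nematode table of PR has 10131 genes, that of M36 has 799, and both have 779. The nematode tables hold infected libraries alone.

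None of the gene identifiers matched the reference table (0 of 34725 tomato identifiers, 0 nematode identifiers, 41476 genes in the table). Gene names and descriptions were therefore not used here, the 40 gene lists fixed before the data were examined could not be tested, and genes are given by identifier. The rule for naming genes, also fixed before the data were examined, then allows 2 identifiers that rose and 2 that fell per comparison. These were those with the largest log2 fold change among genes past the threshold, with a mean of at least 5 CPM (counts scaled to a common library size) over the groups, or 50 CPM for nematode genes, and no overlap in CPM between the groups.

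Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, scaled by TMM (trimmed mean of M values) and tested by the quasi-likelihood F test, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The SE given with a log2 fold change was derived from that test, as its absolute value over the square root of F. It is an approximation and not an output of edgeR. Each table was fitted as a whole with 1 mean per group, so that the groups shared 1 estimate of the spread. The PR tomato fit had 22 libraries and 23086 tested genes, the M36 tomato fit 8 libraries and 21499 genes, and the joint tomato fit 30 libraries and 22795 genes. The PR nematode fit had 10 libraries and 3922 genes, and the joint nematode fit 14 libraries and 762 genes. The biological coefficient of variation was 0.298, 0.288, 0.295, 0.402 and 0.322 in these fits. The labels do not say what a replicate number shares. Deviations from the group means of PR tomato libraries with the same number correlated between infected and uninfected roots at each stage (0.59, 0.41, 0.32, 0.23 and 0.29 at stages 1 to 5). The fit with replicate number as a block is therefore given beside the PR infection responses of stages 2 to 5. In M36 these correlations were -0.02 and 0.09 at stages 1 and 2. Over all pairs of groups they were above 0.1 in 38 of 55 PR tomato pairs, 3 of 6 M36 tomato pairs and 4 of 10 PR nematode pairs. Scaling factors spanned 0.687 to 2.29 in the PR nematode fit and 0.916 to 1.06 in the PR tomato fit.

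The nematode share of a library was its nematode counts over nematode plus tomato counts, with exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error alone, since reads without molecular identifiers are not independent molecules. This limit weighs most on bounds that rest on the 3 libraries with few low counts described below. A gene with no counts in a group was given a bound against a floor of 3 counts over the group. For a gene with few counts in a group the ratio was given with an exact counting interval. Gene groups were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation, and with fry, and adjusted over 15 tests. Fits under other settings, or without a library, repeated camera with the preset correlation alone. The estimated correlations were 0.075 to 0.33, and with them 11 of the 15 tests were no longer past the threshold. The camera p-values with the preset correlation may therefore be too small.

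Alternatives set before the data were examined were RLE and upper quartile scaling, no filter, a filter of 10 CPM in 2 libraries, DESeq2 1.42.0, the 4 libraries of a comparison alone, replicate number as a block, an absolute log2 fold change of at least 1, tomato counts as library sizes of nematode genes, and leaving out each library. Chosen after the data were seen were voom with sample quality weights, a fit without the 3 libraries with few low counts, the line differences at stages 1 and 2 in place of day 0, the changes of the PR response between stages, the added nematode comparisons and the gene groups of the late response. When a group was left with 1 library, that library was assumed to vary like those of the other groups.

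The tests were checked on simulated counts, drawn at random from each gene's mean over all groups with a spread common to all genes. In the first group of a comparison the mean was altered for 100 genes each at 2-fold and 4-fold. At PR stage 3, 4 and 56 of 100 were called. In M36 at stage 2, 6 and 77 of 100 were called. For nematode genes at stage 3 against stage 2, 0 and 3 of 100 were called, and between M36 and PR at stage 2, 4 and 39 of 100. Of the altered genes 0 were called in the wrong direction. In these simulated counts changes of 2-fold were thus mostly not called with 2 libraries per group. The simulation left out differences in spread between genes, the correlation of replicate numbers and the libraries with few low counts. Detection in the real data may therefore differ. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.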

Results

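Roots of tomato (Solanum lycopersicum) were sequenced with and without infection by the root-knot nematode Meloidogyne incognita, a sedentary parasite whose second-stage juveniles (J2) enter the root and induce feeding cells and galls. Pusa Ruby (PR), the susceptible cultivar, was followed through 5 stages after inoculation, and M36, a resistant transgenic line of MM, through stages 1 and 2. Stage 1 covered days 1, 2 and 3 after inoculation, stage 2 days 5, 6 and 7, stage 3 days 13, 14 and 15, stage 4 days 18, 19 and 20, and stage 5 days 26, 27 and 28. Each infected group had an uninfected group of the same stage, which received water, and PR roots were also taken at day 0. Every group had 2 libraries. Counts were given separately for tomato genes and for nematode genes of the same libraries.

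Tomato counts per library ranged from 4438200 to 39248873 in PR and from 7539789 to 17568526 in M36. Replicate 1 of a PR group was deeper than replicate 2 in every group, at 23432548 to 39248873 against 4438200 to 20514690. Nematode counts were far fewer. They ranged from 2690 to 1913873 in the infected PR libraries and from 1969 to 8212 in the infected M36 libraries. Replicate 1 of infected PR stages 2, 4 and 5 held few low counts. Between 310 and 381 tomato genes had a count of 1 to 3 in these 3 libraries, against 1377 to 2640 in the other 19 PR libraries, and their nematode counts had the same gap (102 to 506 genes against 1368 to 3155). Replicates of every group differed by more than sampling noise, with a chi-square over its degrees of freedom of at least 14.5.

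**Figure D1:**
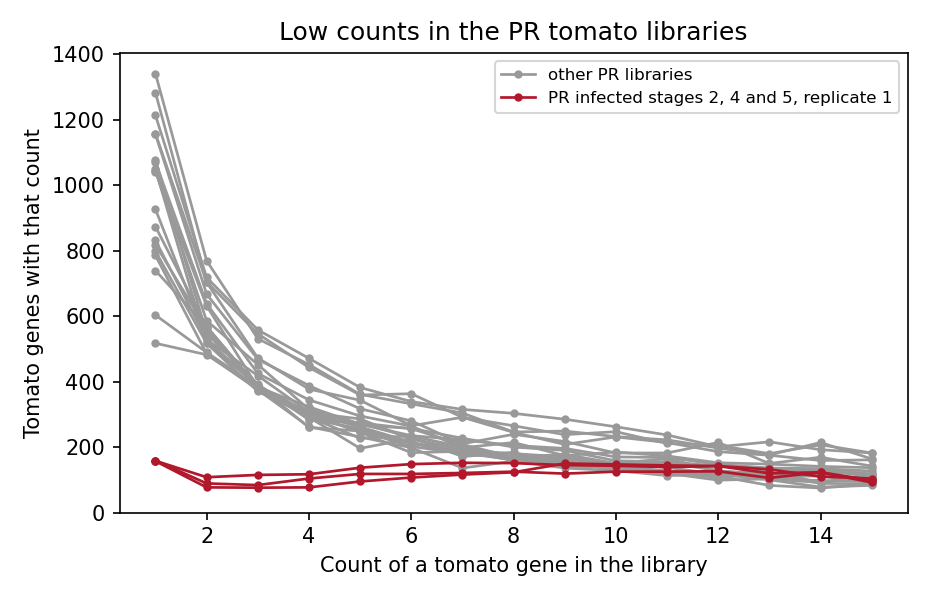
Number of tomato genes (vertical axis) with each count from 1 to 15 (horizontal axis) in the 22 PR libraries, 1 line per library. Replicate 1 of infected stages 2, 4 and 5 (red) had 157 to 159 genes with a count of 1, fewer than any other PR library (grey).

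The share of nematode counts, taken over nematode plus tomato counts, measured how much parasite RNA the infected roots held. In PR it was 0.0490% ± 0.0252 (SD, n = 2) at stage 1 and 0.101% ± 0.0748 (SD, n = 2) at stage 2. It was 0.618% ± 0.0450 at stage 3, 1.38% ± 0.378 at stage 4 and 5.78% ± 0.383 at stage 5 (SD, n = 2 each), which was 118 times the stage 1 mean. Without replicate 1 or replicate 2 of PR stage 1 this ratio was 185 or 86.5. The exact (Clopper-Pearson) 95% intervals of single libraries were narrow. For PR stage 1 replicate 2, which had 3381 nematode counts, the interval was 0.0302 to 0.0323%. The 2 libraries of stages 1 and 2 differed by more than these intervals, 0.0668% against 0.0312% at stage 1 and 0.154% against 0.0481% at stage 2. The stage 2 values overlapped those of stage 1, whereas both libraries of stages 3, 4 and 5 lay above every library of the stages before. With 2 libraries per stage the smallest two-sided p of an exact permutation test between 2 stages is 0.333, so none was made. Uninfected libraries have no nematode columns here, so no background was measured.

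**Figure D2:**
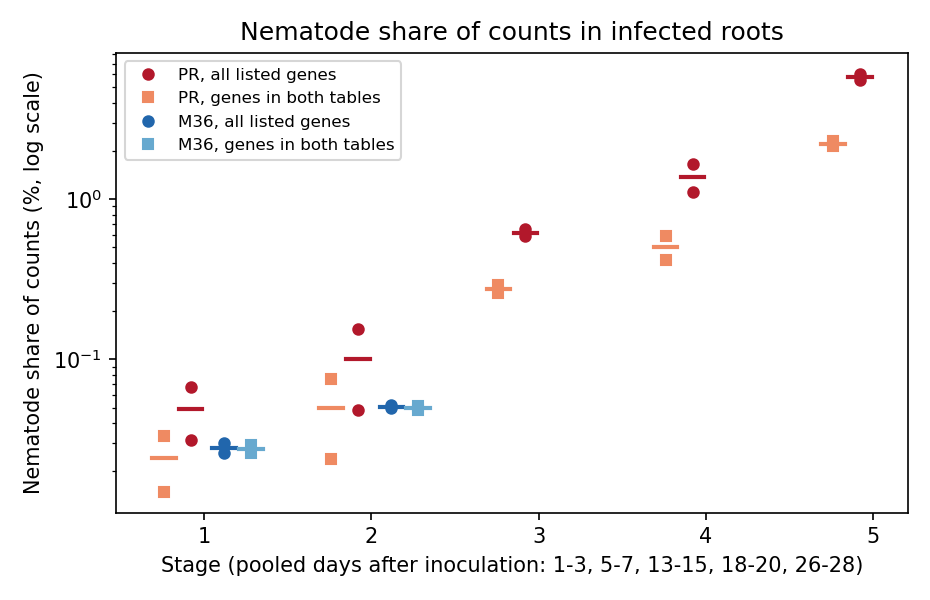
Nematode share of counts in percent (log scale) against stage in infected PR and M36 roots; points are libraries and bars are means of 2. The PR share rose from a mean of 0.0490% at stage 1 to 5.78% at stage 5, and the stage 2 means of PR and M36 were 0.101% and 0.0506% over all listed genes and 0.0496% and 0.0499% over genes in both nematode tables.

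Over the genes listed, M36 roots had nematode shares of 0.0281% ± 0.00276 at stage 1 and 0.0506% ± 0.00153 at stage 2 (SD, n = 2 each). The M36 nematode table lists 799 genes and that of PR lists 10131, so the lines were compared over the 779 genes in both. Over these genes the share was 0.0277% ± 0.00231 in M36 and 0.0241% ± 0.0129 in PR at stage 1, and 0.0499% ± 0.00192 in M36 and 0.0496% ± 0.0364 in PR at stage 2 (SD, n = 2 each). Over these genes the M36 libraries lay between the 2 PR libraries at both stages. The shared genes hold nearly all listed nematode counts of M36 (0.0277% of 0.0281% at stage 1) but fewer of those of PR (0.0241% of 0.0490%), so this comparison favours M36. Genes with fewer than 11 counts in total are not listed, so the M36 share over all genes is not known. Over all listed genes both M36 libraries of stage 1 (0.0300% and 0.0261%) lay below both PR libraries, and those of stage 2 (0.0495% and 0.0517%) lay between them, but the longer PR list was selected with the later stages included. The nematode load of the lines was therefore not ranked. M36 roots of later stages were not analysed here.

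The first question for the host was which tomato genes differed between infected and uninfected PR roots at each stage. No gene passed the threshold at stage 1 (days 1 to 3). At stage 2, 26 genes were higher and 0 lower in infected roots. The 2 with the largest rise under the naming rule were Solyc01g090810.2 and Solyc09g005400.2. Solyc01g090810.2 rose from 4.30 ± 1.69 to 79.4 ± 48.8 CPM (SD, n = 2), a log2 fold change of 4.23 (SE 0.65, edgeR adjusted p = 0.0273). Solyc09g005400.2 rose from 13.4 ± 2.52 to 221 ± 66.5 CPM (SD, n = 2), a log2 fold change of 4.04 (SE 0.73, edgeR adjusted p = 0.0488). Both stayed high afterwards, with log2 fold changes of 5.28, 5.34 and 4.86 for Solyc01g090810.2 and 6.10, 4.64 and 6.23 for Solyc09g005400.2 at stages 3, 4 and 5. Of the 26 genes, 25 were also called higher at stage 3, 25 at stage 4 and 25 at stage 5, and 23 at all 3, where independent lists would share 0.961, 1.34 and 1.84 genes with the single stages. The stages shared 1 fit and 1 spread estimate per gene, which by itself favours shared calls.

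At stage 1, 282 of 23086 genes had an unadjusted p under 0.05 in edgeR, and DESeq2 and voom called 0 genes. Exact p-values of unchanged genes would put a share of 0.05 there, and 282 is fewer. The edgeR p-values of this comparison may therefore be too large. A fit with replicate number as a block also called 0 genes. The stage 2 count depended on the fit. It was 0 without replicate 1 of infected stage 2, a library with few low counts, 0 without replicate 1 of uninfected stage 2, 12 without replicate 2 of uninfected stage 2 and 72 without replicate 2 of infected stage 2; DESeq2 called 287 genes, voom 10, a fit of the 4 libraries alone 0 and a fit with replicate number as a block 149. Neither named gene was called without replicate 1 of uninfected stage 2 (edgeR adjusted p of 0.599 for Solyc01g090810.2 and 0.685 for Solyc09g005400.2), replicate 2 of uninfected stage 2 (0.0877 and 0.205) or replicate 1 of infected stage 2 (0.175 and 0.204).

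From stage 3 on the PR response was large and went both ways. Stage 3 (days 13 to 15) had 1950 genes past the threshold, 853 higher and 1097 lower. Stage 4 had 2343, 1192 higher and 1151 lower, and stage 5 had 3276, 1631 higher and 1645 lower, of 23086 tested. Several of the genes that fell almost disappeared from infected roots. At stage 3 Solyc05g008150.2 had 16.7 ± 7.54 CPM (SD, n = 2) in uninfected roots and 2 counts in total in infected roots, 429-fold lower with a counting interval of 119 to 3540 (edgeR adjusted p = 0.000442). Solyc03g090990.1 went from 17.1 ± 9.35 to 0.0891 ± 0.0276 CPM (SD, n = 2; log2 fold change -7.42, SE 0.96). Among the genes that rose, Solyc07g007750.2 went from 0.101 ± 0.142 to 19.9 ± 15.8 CPM (log2 fold change 6.87, SE 1.62) and Solyc08g062450.1 from 0.179 ± 0.0827 to 12.3 ± 6.30 CPM (log2 fold change 6.38, SE 1.42; SD, n = 2). The call of Solyc07g007750.2 ended without replicate 1 or 2 of uninfected stage 3 or replicate 2 of infected stage 3 (edgeR adjusted p of 0.141, 0.0783 and 0.0654). That of Solyc08g062450.1 ended without replicate 1 of uninfected or infected stage 3 (edgeR adjusted p of 0.165 and 0.0599).

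At stage 4 the largest rises under the naming rule were those of Solyc08g068630.2 and Solyc02g086300.2. Solyc02g086300.2 had 66.4 ± 47.5 CPM in infected and 0.875 ± 0.519 CPM in uninfected roots (SD, n = 2; log2 fold change 6.2, SE 1.38, edgeR adjusted p = 0.0103). Solyc08g068630.2 had 10.1 ± 8.05 CPM (SD, n = 2) in infected roots and 3 counts in total in uninfected roots, 176-fold higher with a counting interval of 60.3 to 855. The largest falls under the same rule were those of Solyc03g097620.1 and Solyc01g107710.2, with 33.3 ± 21.5 and 13.0 ± 1.05 CPM in uninfected roots (SD, n = 2) and 1 count each in infected roots. They were 1140-fold and 442-fold lower, with counting intervals of 204 to 44900 and 79.4 to 17500. At stage 5 Solyc04g081860.2 and Solyc10g074840.1 had no counts in either infected library and 24.3 ± 1.01 and 15.0 ± 1.04 CPM in uninfected roots (SD, n = 2). Against a floor of 3 counts over the group they were at least 286-fold and at least 177-fold lower. In replicate 1 of infected stage 5 rarely detected genes that were seen had a median of 9 counts, so these bounds hold for counts and not for molecules. Solyc11g011590.1 rose from 0.103 ± 0.0700 to 13.1 ± 3.84 CPM (SD, n = 2; log2 fold change 7.08, SE 1.16, edgeR adjusted p = 0.00112). Solyc01g100440.1 rose to 14.1 ± 16.6 CPM (SD, n = 2) from 1 count in uninfected roots, 812-fold higher with a counting interval of 146 to 32100, but its 2 infected libraries had 783 and 12 counts. Solyc02g086300.2, Solyc03g097620.1, Solyc01g100440.1 and Solyc10g074840.1 were no longer called without the 3 libraries with few low counts (edgeR adjusted p of 0.0889, 0.0836, 0.0774 and 0.157), nor without replicate 1 of infected roots of their stage alone (0.0693, 0.0687, 0.0559 and 0.130). The call of Solyc02g086300.2 also ended without replicate 1 or 2 of uninfected stage 4 (edgeR adjusted p of 0.0738 and 0.111).

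**Figure D3:**
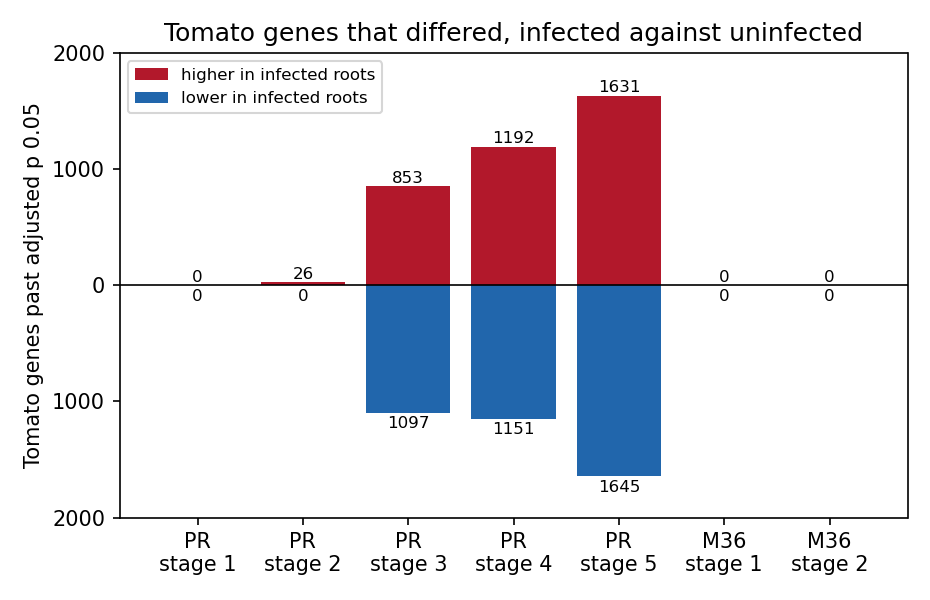
Number of tomato genes (vertical axis) higher (red, above 0) or lower (blue, below 0) in infected than in uninfected roots at an edgeR adjusted p under 0.05, for each line and stage (horizontal axis). PR had 1950, 2343 and 3276 genes at stages 3, 4 and 5, and M36 had 0 at stages 1 and 2.

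The size of these counts depended on single libraries. Without the 3 libraries with few low counts, stage 4 had 960 genes and stage 5 had 1204, of which 865 and 1111 were among the genes called with all libraries. Stage 3, whose own 4 libraries include none of these but share the spread estimate, had 2425 genes without them, 1877 of them among the 1950. At stage 3 leaving out infected replicate 1, uninfected replicate 1 or infected replicate 2 gave 810, 831 or 1245 genes. At stage 4 leaving out infected replicate 1, uninfected replicate 2 or uninfected replicate 1 gave 681, 907 or 1017 genes. At stage 5 leaving out infected replicate 1, uninfected replicate 2 or uninfected replicate 1 gave 1067, 1604 or 1726 genes. Fits of the 4 libraries of a stage alone gave 1179 genes at stage 3 and 1197 at stage 5, and voom with sample quality weights gave 3793 genes at stage 4. With replicate number as a block, stages 3, 4 and 5 had 2878, 3444 and 4569 genes.

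The 3 late stages shared more genes than independent lists would. Of the genes called higher, 553 were shared by stages 3 and 4, 662 by stages 3 and 5 and 844 by stages 4 and 5, where independent lists would share 44.0, 60.3 and 84.2. Of the genes called lower, 730, 873 and 820 were shared, against 54.7, 78.2 and 82.0. Each stage had its own uninfected libraries, so these overlaps did not come from shared controls. Among these 3 stages 2 genes were called in opposite directions. In all, 489 genes were called higher and 653 lower at every one of stages 3, 4 and 5, of 2106 and 2123 called at any of them. The median log2 fold change of the 489 genes was 2.06, 2.08 and 2.25 at stages 3, 4 and 5. That of the 653 genes was -2.71, -2.78 and -3.10, or -2.70, -2.62 and -2.93 with genes at 0 in a group set to their bound. The change of the response from stage 3 to stage 5 was tested directly, and no gene passed in edgeR (766 at an unadjusted p under 0.05). DESeq2 called 15. The 766 genes were below 0.05 of those tested, so these edgeR p-values may be too large.

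Between stages 2 and 3 the response did change. The response of 111 genes differed between these stages, with 10 higher and 101 lower at stage 3. All 101 were called lower at stage 3, with a median log2 fold change of -4.71 (-4.60 with bounds) there and -0.20 at stage 2. The count was 0 without replicate 1 of uninfected stage 2, 3 without replicate 1 of uninfected stage 3, 12 without replicate 2 of uninfected stage 2, 17 and 15 without replicate 1 or 2 of infected stage 3, 56 without replicate 2 of infected stage 2 and 187 without replicate 2 of uninfected stage 3. DESeq2 called 385 genes and a fit with replicate number as a block 186.

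The 489 and 653 late-response genes, which were defined on libraries of stages 3 to 5 after the data were seen, were then followed in the earlier stages, which use other libraries. In PR at stage 2, 457 of the 489 (93.5%) had a positive log2 fold change, with a median of 1.08 (quartiles 0.59 and 1.70), and 23 were called; 275 passed when adjusted over the list alone. As a set they stood above other genes (camera adjusted p = 8.92e-81, and adjusted p = 0.000265 with an estimated correlation). Of the 653 genes, 573 (87.7%) were below 0 at stage 2, with a median of -0.53 (camera adjusted p = 2.48e-20, and adjusted p = 0.0711 with an estimated correlation). At PR stage 1 the medians were 0.20 and -0.09 (camera adjusted p = 6.72e-14 and 0.000683, and adjusted p = 0.0691 and 0.425 with an estimated correlation). The median of the 653 genes at stage 1 was 0.02 without replicate 2 of infected stage 1 (camera adjusted p = 0.96) and -0.29 without replicate 1, and that of the 489 genes was 0.13 without replicate 1. Of the 26 genes called at PR stage 2, 25 were above 0 at PR stage 1, with a median of 0.38 (camera adjusted p = 7.27e-14, and adjusted p = 0.0231 with an estimated correlation; fry adjusted p = 0.0523).

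**Figure D4:**
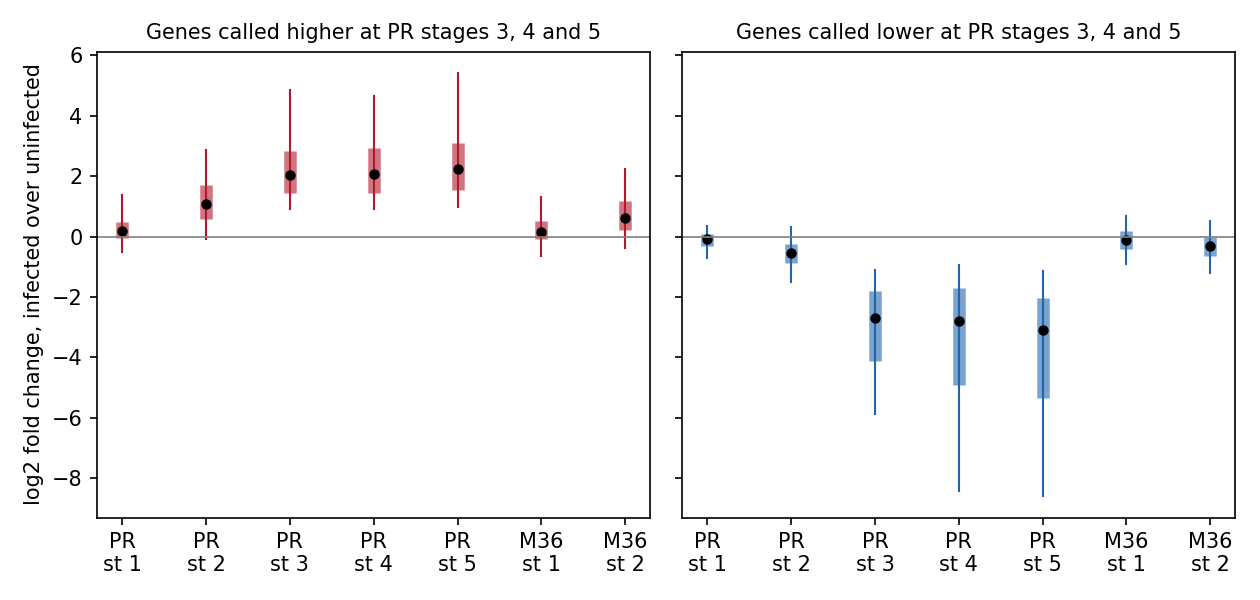
Log2 fold change of infected over uninfected roots (vertical axis) for the 489 genes called higher (left) and the 653 called lower (right) at PR stages 3, 4 and 5, in each line and stage (horizontal axis). Dots are medians, thick bars the quartiles and thin lines the range from the lowest to the highest 5%; the medians at stage 2 were 1.08 and -0.53 in PR and 0.63 and -0.32 in M36.

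In M36 no tomato gene passed the threshold in edgeR at stage 1 (673 of 21499 genes at an unadjusted p under 0.05) or at stage 2 (2049 at an unadjusted p under 0.05). The stage 1 count was below 0.05 of the genes tested, so its p-values may be too large. Voom called 0 genes at both stages. DESeq2 called 5 genes at stage 1 and 246 at stage 2, of which 208 were higher and 38 lower. The late-response genes of PR were followed in M36 as sets; 0 of their members were called, and no set passed with an estimated correlation or with fry. At stage 2, 403 of 467 tested members of the rising group (86.3%) were above 0, with a median log2 fold change of 0.63 (quartiles 0.21 and 1.19), and 43 passed when adjusted over the list alone (camera adjusted p = 1.72e-27, and adjusted p = 0.0711 with an estimated correlation). Of 652 tested members of the falling group, 502 (77.0%) were below 0, with a median of -0.32 (camera adjusted p = 1.47e-09, and adjusted p = 0.154 with an estimated correlation). At stage 1, 308 of 467 were above 0 and 389 of 652 below 0, and the medians were 0.16 and -0.11 (camera adjusted p = 5.76e-06 and 0.000939, and adjusted p = 0.306 and 0.355 with an estimated correlation). Without replicate 2 of infected M36 stage 1 the rising median was 0.03 (camera adjusted p = 0.0504), and without replicate 2 of uninfected M36 stage 1 the falling median was -0.09 (camera adjusted p = 0.0504); the latter was -0.18 without replicate 1 of infected M36 stage 1. At stage 2 the falling median was -0.09 without replicate 1 of uninfected M36 (camera adjusted p = 0.0176), and the rising median was 0.35 without replicate 2 of infected M36 (camera adjusted p = 2.5e-10). Of the 26 genes called at PR stage 2, 24 were tested in M36, and 23 of them were above 0 at stage 2 with a median of 1.40 (camera adjusted p = 1.76e-18, and adjusted p = 0.0711 with an estimated correlation), or 0.86 without replicate 2 of infected M36. In M36 at stage 2 Solyc01g090810.2 had a log2 fold change of 1.93 (SE 0.99) and Solyc09g005400.2 of 1.78 (SE 1.22), neither called (edgeR adjusted p = 0.574 and 0.661).

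Whether infection changed tomato genes differently in M36 and PR, the comparison of resistant with susceptible roots that the series names, was tested as an interaction. No gene passed at stage 1 (235 of 22795 genes at an unadjusted p under 0.05 in edgeR) or at stage 2 (841 at an unadjusted p under 0.05), and DESeq2 called 0 at both. The 235 and 841 genes were below 0.05 of those tested, so these edgeR p-values may be too large. The late-response genes were chosen by their response in PR, which by itself favours a smaller response in M36. At stage 2 the rising group had a median difference of -0.32 (M36 minus PR, quartiles -0.87 and 0.08), with 351 of 489 below 0. The camera adjusted p was 9.34e-11, or 0.0711 with an estimated correlation, and the fry adjusted p was 0.139. The falling group differed by a median of 0.22, with 420 of 653 above 0 (camera adjusted p = 0.00117, and adjusted p = 0.425 with an estimated correlation). The difference of the falling group was no longer past the threshold without replicate 1 of infected PR stage 2 (median 0.14, camera adjusted p = 0.34) or without replicate 2 of uninfected M36 stage 2 (median 0.10, camera adjusted p = 0.979). It was 0.46 without replicate 1 of uninfected M36 stage 2 and 0.36 without replicate 2 of infected PR stage 2. The difference of the rising group was -0.16 without replicate 1 of infected M36 stage 2 (camera adjusted p = 0.000309) and -0.55 without replicate 2. At stage 1 neither group differed (camera adjusted p = 0.305 and 0.733; medians -0.05 and -0.03). The falling group passed without replicate 2 of infected PR stage 1 (median -0.16, camera adjusted p = 0.0115), but its median was 0.18 without replicate 1 (camera adjusted p = 0.147). The rising group passed without that library (median -0.09, camera adjusted p = 0.0489) or replicate 2 of infected M36 stage 1 (median -0.23, camera adjusted p = 0.0481), but its median was 0.02 and 0.06 without replicate 1 of these groups (camera adjusted p = 0.883 and 0.517). Line and table were the same split, so processing that differed between the tables cannot be told apart from the line in levels. The parent of M36 is MM and not PR, so resistance cannot be told apart from background in any comparison of M36 with PR.

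Uninfected M36 and PR roots of the same stage were compared as the baseline of the lines. M36 and MM roots of day 0 were not analysed here, so differences of background cannot be told apart from those of the transgene. At stage 1, 39 genes differed, 7 higher and 32 lower in M36, and at stage 2, 43 differed, 12 higher and 31 lower. The comparisons shared 5 of the higher and 27 of the lower genes, where independent lists would share 0.00369 and 0.0435. They also shared 1 fit and 1 spread estimate per gene, which by itself favours shared calls. Several genes were expressed in PR and had no counts in the uninfected M36 libraries of the stage compared. Solyc11g028010.1 had 71.4 ± 21.7 CPM at stage 1 and 76.5 ± 22.7 CPM at stage 2 in PR (SD, n = 2) and 0 counts in all 4 uninfected M36 libraries, at least 723-fold and at least 697-fold lower against 3 counts over the group. Solyc05g013880.1 at stage 1 (81.6 ± 32.3 CPM in PR; SD, n = 2) and Solyc07g008110.2 at stage 2 (67 ± 13.6 CPM in PR; SD, n = 2) were at least 827-fold and at least 611-fold lower. Solyc12g087830.1 was higher in M36 at both stages, with 17.6 ± 3.53 against 0.534 ± 0.232 CPM at stage 1 (SD, n = 2; log2 fold change 5.13, SE 0.47, edgeR adjusted p = 8.46e-06) and a log2 fold change of 4.05 (SE 0.43) at stage 2. Solyc08g059700.1 was higher at stage 1 (log2 fold change 4.30, SE 0.55) and Solyc01g081250.2 at stage 2 (log2 fold change 5.65, SE 0.86).

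The line counts fell to 20 and 15 at stage 1 without replicate 1 or replicate 2 of uninfected M36. At stage 2 they were 15 and 69 without replicate 1 or replicate 2 of uninfected M36, and 25 and 28 without replicate 1 or replicate 2 of uninfected PR. DESeq2 called 74 and 142 genes. The call of Solyc01g081250.2 ended without replicate 1 or 2 of uninfected PR stage 2 (edgeR adjusted p of 0.175 and 0.0518) or replicate 1 of uninfected M36 stage 2 (0.0752).

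Change with plant age, without infection, was measured in uninfected PR roots, stage 5 against day 0, where age and the water treatment cannot be told apart. It covered 405 genes, 213 higher and 192 lower at stage 5, against 1521 genes in a fit with replicate number as a block. Solyc08g007430.1 fell from 49.8 ± 15.3 to 0.168 ± 0.0495 CPM (SD, n = 2; log2 fold change -8.24, SE 1.93, edgeR adjusted p = 0.0465) and Solyc04g025750.2 from 46.7 ± 27.9 to 0.759 ± 0.360 CPM (SD, n = 2; log2 fold change -6.00, SE 1.14, edgeR adjusted p = 0.0216). Solyc04g072280.2 rose from 0.700 ± 0.174 to 41.2 ± 48.3 CPM (SD, n = 2; log2 fold change 5.97, SE 1.3) and Solyc04g079260.2 from 0.159 ± 0.225 to 18.6 ± 24.7 CPM (SD, n = 2; log2 fold change 6.24, SE 1.38). The count was 44 and 1 without replicate 1 or replicate 2 of day 0 and 31 and 44 without replicate 1 or replicate 2 of uninfected stage 5; DESeq2 called 1789 genes and the fit without the 3 libraries with few low counts 788. The calls of Solyc08g007430.1 and Solyc04g025750.2 ended without replicate 1 or 2 of day 0 (edgeR adjusted p of 0.133 and 0.180, and 0.0845 and 0.0986) or replicate 1 or 2 of uninfected stage 5 (0.309 and 0.221, and 0.208 and 0.122). Those of Solyc04g072280.2 and Solyc04g079260.2 ended without replicate 1 or 2 of day 0 (0.206 and 0.220, and 0.162 and 0.239) or replicate 2 of uninfected stage 5 (0.221 and 0.373).

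With tomato counts as library sizes, which keep the rising parasite load in the values and test more genes, 7780 nematode genes differed among the 5 PR stages. Scaled within nematode counts, 1334 of 3922 tested nematode genes differed among these stages. Their highest mean CPM fell at stage 1 for 245 genes (18.4%), at stage 2 for 72 (5.40%), at stage 3 for 336 (25.2%), at stage 4 for 371 (27.8%) and at stage 5 for 310 (23.2%). Of the 10131 genes listed, 4426 had no counts in any library of stages 1 and 2. These libraries had 2690 to 43702 nematode counts each, against 337806 and 1913873 at stage 5. The list was also selected with the later stages included, so this absence may reflect depth alone. The number of genes that differed among stages depended on the fit. The count was 864 without replicate 1 of infected stage 2 and 2209 without replicate 2, 543 without the 3 libraries with few low counts and 655 in DESeq2.

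Between consecutive stages, stage 3 differed from stage 2 at 1330 nematode genes, 1222 higher and 108 lower. Minc00885 and Minc09650 had no counts at stage 2 and 11900 ± 7950 and 6920 ± 4420 CPM of nematode counts at stage 3 (SD, n = 2), at least 226-fold and at least 132-fold higher. Stage 2 differed from stage 1 at 182 genes, 27 higher and 155 lower. Minc00239 had no counts at stage 1 and was at least 16.2-fold higher at stage 2, and Minc10779 had no counts at stage 2 and was at least 33.4-fold lower. Stage 4 differed from stage 3 at 102 genes, 77 higher and 25 lower. Minc11260 and Minc08754 were at least 358-fold and at least 347-fold higher at stage 4, with 5100 ± 896 and 4950 ± 606 CPM against 0 counts at stage 3 (SD, n = 2). Minc13027 had 127 ± 39.5 CPM at stage 3 (SD, n = 2) and no counts at stage 4, at least 12.3-fold lower. Stage 5 differed from stage 4 at 149 genes, 48 higher and 101 lower. Minc08180 and Minc06216 were at least 623-fold and at least 272-fold higher at stage 5, with 6390 ± 3280 and 2790 ± 1570 CPM against 0 counts at stage 4 (SD, n = 2). Minc16382 fell from 960 ± 21.5 to 26.8 ± 1.79 CPM (SD, n = 2; log2 fold change -5.11, SE 0.74, edgeR adjusted p = 3.57e-07). In replicate 1 of infected stages 2 and 4 rarely detected nematode genes that were seen had a median of 10 counts. Bounds of genes at 0 at stage 2 or 4 thus hold for counts and not for molecules. The call of Minc00239 ended without stage 1 replicate 1 (edgeR adjusted p = 0.38), that of Minc10779 without stage 2 replicate 1 (0.745) and that of Minc13027 without stage 4 replicate 1 (0.310).

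The comparisons with stage 2 rested on replicate 1 of infected stage 2. Without it, stage 3 against stage 2 called 28 genes and stage 2 against stage 1 called 1 gene; the latter was 0 without replicate 1 of stage 1 and 427 without replicate 2 of stage 2. Stage 3 against stage 2 called 553 and 842 genes without replicate 1 or replicate 2 of stage 3. Stage 4 against stage 3 called 40 to 191 genes, and stage 5 against stage 4 called 80 to 311, when each library was left out. The lowest came without stage 3 replicate 2 and stage 5 replicate 1 and the highest, in both, without stage 4 replicate 2. Without stage 3 replicate 1 or stage 4 replicate 1, stage 4 against stage 3 called 57 and 51 genes, and without stage 4 replicate 1 or stage 5 replicate 2, stage 5 against stage 4 called 92 and 82. DESeq2 called 120, 192, 43 and 73 genes in the 4 steps from stage 1 to stage 5, and edgeR without the 3 libraries with few low counts called 1, 7, 57 and 71. The split of higher and lower calls depended on the scaling. With RLE it was 382 higher and 154 lower for stage 3 against stage 2 and 118 and 16 for stage 4 against stage 3. Per tomato count, where the rising parasite load stays in the values, 128 genes were higher and 2 lower at stage 2, 2907 and 17 at stage 3, 178 and 0 at stage 4 and 3844 and 25 at stage 5, each against the stage before. The median log2 fold change of all nematode genes from stage 2 to 3 was 2.12 with TMM and 1.37 with RLE, and RLE moved the medians of the other 3 steps by -0.16, 0.49 and -0.10.

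Nematode genes were last compared between M36 and PR roots, over 762 tested genes listed in both tables. A gene had to reach the M36 list, which holds 799 genes against 10131 for PR. That selection by itself favours genes that are higher in M36, so the splits by direction below are not a fair measure. At stage 1, 4 genes differed, 3 higher and 1 lower in M36. Minc01079 and Minc13172 had no counts in PR, and 6 and 9 and then 10 and 3 counts in the M36 replicates, at least 12.4-fold and at least 8.42-fold higher, and Minc06157 was lower in M36 (762 ± 485 against 7750 ± 15.5 CPM; SD, n = 2; log2 fold change -3.19, SE 0.76). Leaving out 1 library could end each of these calls: without PR replicate 1 the edgeR adjusted p was 0.741, 0.741 and 0.427, and without M36 replicate 2 it was 0.184, 0.104 and 0.340. Without PR replicate 2 it was 0.0732 for both Minc13172 and Minc06157, and without M36 replicate 1 it was 0.538 and 0.307. At stage 2, 221 genes differed, 181 higher and 40 lower in M36. Minc04488 and Minc02411 had no counts in PR and 5230 ± 2120 and 4440 ± 277 CPM in M36 (SD, n = 2), at least 41.2-fold and at least 35.0-fold higher. Rarely detected nematode genes seen in replicate 1 of infected PR stage 2 had a median of 10 counts. Bounds against PR stage 2 thus hold for counts and not for molecules. Minc11162 was lower in M36, at 1990 ± 1550 against 16400 ± 2410 CPM (SD, n = 2; log2 fold change -2.98, SE 0.58, edgeR adjusted p = 0.000336). Without PR stage 2 replicate 1 Minc04488 and Minc02411 were no longer called (edgeR adjusted p = 0.283 for both). Of the 181 genes, 98 had no counts in either PR library of stage 2, and the median log2 fold change was 3.13 with such genes at their bound.

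M36 stage 2 was then set against the stage 1 libraries over the same genes, a comparison chosen after the data were seen. It differed from M36 stage 1 at 0 genes in edgeR and 0 in DESeq2. In edgeR 22 genes had an unadjusted p under 0.05, below 0.05 of those tested, so these p-values may be too large. M36 stage 2 differed from PR stage 1 at 14 genes, 11 higher and 3 lower. Minc11102 had no counts at PR stage 1 and was at least 19.8-fold higher, and Minc19131 was lower (log2 fold change -3.36, SE 0.62). The call of Minc11102 ended without PR stage 1 replicate 1 or M36 stage 2 replicate 1 (edgeR adjusted p of 0.538 and 0.110), and that of Minc19131 without M36 stage 2 replicate 1 (0.0601). The change from stage 1 to stage 2 differed between M36 and PR roots at 44 genes, 40 higher and 4 lower in M36. These counts also rested on replicate 1 of infected PR stage 2, without which the stage 2 comparison called 2 genes and the interaction 0. Without replicate 1 of infected M36 stage 2 the stage 2 comparison called 123 genes. The interaction called 0 genes without replicate 1 of infected PR stage 1, 77 without replicate 2 of infected PR stage 2, 13 without replicate 2 of infected M36 stage 1, and 10 and 27 without replicate 1 or 2 of infected M36 stage 2. M36 stage 2 against PR stage 1 called 1 gene without replicate 1 of either group and 8 without replicate 2 of either. The stage 1 comparison of the lines called 0 genes without replicate 1 of infected PR stage 1 or replicate 2 of infected M36 stage 1, and 1 without replicate 2 of infected PR stage 1. With RLE scaling the stage 2 split was 231 higher and 10 lower, and the stage 1 comparison called 2 genes, both higher.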

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

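All tests in this part were chosen after the data were seen, and the test of the low-count library replaced a version that had been run and read on genes chosen with the same library. The test of the row filter first used the fit with all libraries alone, and the fit without the 3 libraries was added after its result was read.

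The change of nematode genes from stage 1 to stage 2 differed between M36 and PR roots at 44 genes, 40 higher and 4 lower in M36; it called 0 without replicate 1 of infected PR stage 1, 77 without replicate 2 of infected PR stage 2, 13 without replicate 2 of infected M36 stage 1, and 10 and 27 without replicate 1 or 2 of infected M36 stage 2. M36 stage 2 differed from PR stage 2 at 221 genes but from PR stage 1 at 14 over the same genes, while without the 3 libraries with few low counts it differed at 9 and 23, so the row filter of the M36 table stays open. Replicate 1 of infected PR stage 2, one of these libraries, stays open too: without it the interaction called 0 genes and the stage 2 comparison 2, although the 234 genes higher in M36 with replicate 1 as the PR library also took a smaller share of replicate 2 than of PR stage 1 (10.5% against 28.4% and 26.7%, a ratio of 0.38). A biological candidate explanation is that nematodes in M36 roots at stage 2 may keep the profile of stage 1; with 44 genes in the interaction, and 0 genes between M36 stages 2 and 1 in edgeR (22 at an unadjusted p under 0.05; 0 in DESeq2), it cannot be told apart from the effects of that library and the row filter, because 1 other PR library of the stage is too few.

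The response of PR roots to infection differed between stages 2 and 3 at 111 tomato genes, by a test of the difference itself, 10 higher and 101 lower at stage 3. The count was 0, 12, 3 and 187 without replicate 1 or 2 of uninfected stage 2 and replicate 1 or 2 of uninfected stage 3, 56 without replicate 2 of infected stage 2, and 17 and 15 without replicate 1 or 2 of infected stage 3.

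The genes called higher or lower at PR stages 3, 4 and 5 were chosen by their response in PR, which by itself favours a smaller response in M36. At stage 2 the response of those called higher had a median difference of -0.32 on the log2 scale, M36 minus PR (camera adjusted p = 9.34e-11, or 0.0711 with an estimated correlation, and fry adjusted p = 0.139). It was -0.16 without replicate 1 of infected M36 stage 2 and -0.55 without replicate 2. The genes called lower at these stages differed by a median of 0.22 (camera adjusted p = 0.00117, and adjusted p = 0.425 with an estimated correlation). That difference was not past the threshold without replicate 1 of infected PR stage 2 (0.14, camera adjusted p = 0.34) or replicate 2 of uninfected M36 stage 2 (0.10, camera adjusted p = 0.979), and was 0.46 without replicate 1 of uninfected M36 stage 2 and 0.36 without replicate 2 of infected PR stage 2.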

How the results depend on the processing

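Line comparisons at day 0 and the gene lists were planned and not run, for lack of columns and of gene names in the sources used here. Among results with a value, voom, the fit without the 3 libraries with few low counts and every alternative of the added comparisons and gene groups were chosen after the data were seen; the cause of a moved value was not tested. Counts are of genes past the threshold.

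With no filter PR stage 2 gave 45 genes and nematode stage 2 against 1 gave 85. With the 4 libraries alone PR stages 2, 3 and 5 gave 0, 1179 and 1197. With replicate number as a block PR stage 2 gave 149, ageing 1521, nematode stage 2 against 1 319, 4 against 3 200, 5 against 4 228, M36 against PR at stage 1 8, M36 stage 2 against PR stage 1 27 and the response change from stage 2 to 3 186. The block moved no other count of a comparison by over 1.5 times. It ended no call of a gene group by camera with the preset correlation of 0.01, the only group test repeated with it. With an estimated correlation and no block, 11 of the 15 group tests were no longer past the threshold. Outside the PR infection responses equal numbers are not known to mark shared samples. RLE scaling gave 283 for nematode stage 2 against 1, 536 for 3 against 2 and 2 for M36 against PR at stage 1. Tomato library sizes gave 2924, 178 and 3869 for nematode stages 3, 4 and 5 against the stage before and 7780 among all stages.

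DESeq2 gave 287 at PR stage 2, 5 and 246 in M36 at stages 1 and 2, 1789 for ageing, 74 and 142 for the line differences, 385 and 15 for the response changes, and 120, 192, 43 and 73 for consecutive nematode stages. It gave 655 among all nematode stages, 1 for M36 against PR at stage 1 and 29 for the nematode interaction. Voom gave 10 at PR stage 2 and 3793 at stage 4. Without the 3 libraries PR stages 2, 4 and 5 gave 0, 960 and 1204, ageing 788, consecutive nematode stages 1, 7, 57 and 71 and all stages 543. M36 against PR gave 8 at stage 1 and 9 at stage 2, M36 stage 2 gave 1 against M36 stage 1 and 23 against PR stage 1, and the interaction 0.

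Against the top 2000 tomato genes the nematode percentages of PR stages 1 to 5 were 0.0956, 0.194, 1.19, 2.74 and 11.7, and those of M36 0.0544 and 0.0993, because the denominator is smaller. Without the top 10 nematode genes the M36 percentages were 0.0248 and 0.0439.

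Leaving out each library in turn, the counts were 0 to 72, 810 to 1349, 681 to 2021 and 1067 to 3904 at PR stages 2 to 5, and 15 to 35 and 15 to 69 for the line differences. They were 1 to 44 for ageing, 0 to 187 and 0 to 2 for the response changes, and 0 to 427, 28 to 1907, 40 to 191 and 80 to 311 for consecutive nematode stages, with 864 to 2209 among all stages. For M36 against PR they were 0 to 3 at stage 1 and 2 to 279 at stage 2. For M36 stage 2 they were 0 to 1 against M36 stage 1 and 1 to 8 against PR stage 1, and 0 to 77 for the interaction. PR stage 1, both M36 responses and both differences between the lines' responses stayed at 0 in edgeR (282, 673, 2049, 235 and 841 at an unadjusted p under 0.05). Nematode percentages were 0.0312 to 0.0668, 0.0481 to 0.154, 0.586 to 0.650, 1.11 to 1.65 and 5.51 to 6.05 in PR and 0.0261 to 0.0300 and 0.0495 to 0.0517 in M36, and the ratio of PR stage 5 to 1 was 86.5 to 185. The genes called lower late had a median of -0.09 at PR stage 1, and of -0.29 to 0.02 when a library was left out, with 0.02 (camera adjusted p = 0.96) without replicate 2 of infected stage 1. Of 540 values of named genes under alternatives, 432 kept direction and side of the threshold, 108 kept direction and were no longer past it, and 0 turned. Named genes were chosen for the largest changes without overlap between groups, so a turn was unlikely from the start and its absence is no support. RLE scaling moved the median of all nematode genes of M36 against PR by 0.28 and 0.58 at stages 1 and 2. Of the 5 tomato comparisons that stayed at 0, only M36 stage 2 had more than 0.05 of its tested genes at an unadjusted p under 0.05. In M36 at stage 2 edgeR called 0 genes (2049 at an unadjusted p under 0.05, and 246 called by DESeq2). In counts simulated for that comparison, with a spread common to all genes, 6 of 100 changes of 2-fold and 77 of 100 of 4-fold were called.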

Other observations

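In this part the test of nematode reads on tomato genes was set before its result was seen; all other tests were chosen after, and the replicate 2 test of the fold changes replaced a version that had been run and read on genes chosen with the same libraries (it gave a higher percentage and is not used here).

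Genes called in PR lay next to each other in the order of their identifiers more often than random placements of as many genes among those tested. Stages 3, 4 and 5 had 206, 255 and 446 neighbouring pairs against random medians of 83, 118 and 230. The line differences of uninfected roots had 7 pairs at stage 1 and 7 at stage 2, against a random median of 0 in each. The permutation p was 1e-04 for these 5 comparisons, the smallest that 10000 placements can give. Change with plant age in uninfected PR roots had 12 pairs against a random median of 3 (permutation p = 4e-04). PR stage 2 had 1 pair against a random median of 0 (permutation p = 0.03). Neighbouring calls were thus not particular to infection or to the line. A run of 6 genes on chromosome 11, from Solyc11g028000.1 to Solyc11g028180.1, was lower in M36 throughout. At each stage 5 of these genes had no counts in uninfected M36 roots, and with those at their bound the median log2 fold change was -6.19 at stage 1 and -5.92 at stage 2. Chromosome 11 held 9 of the 50 genes that differed between the lines (18.0%, against 6.65% of tested genes; Fisher's exact test, two-sided, adjusted p = 0.0676).

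Replicate 1 of infected PR stages 2, 4 and 5 held few counts of 1 to 3. A limit that set low counts to 0 is argued against by at least 310 tomato genes with such counts in each, and a common multiplier by all 100 whole numbers from 1 to 100 occurring in each. Among rarely detected genes the median of the counts above 0 was at least 6 in these libraries, for tomato and nematode genes alike. In the other PR libraries it was 1 to 2 for tomato and 1 to 4 for nematode genes. Several reads per original molecule could give this, but a lack of counts of 1 to 3 raises this median by itself. The median therefore restates the pattern. These libraries also detected fewer tomato genes than the shallower replicate 2 of their groups. At stages 2, 4 and 5 it was 22719, 22476 and 22493 genes in replicate 1 against 22938, 23432 and 22974 in replicate 2. The other PR libraries of replicate 1 detected 24581 to 25176. Several reads per molecule would go with these values, but that explanation was not tested further and stays open. No biological explanation was tested.

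The 489 genes called higher at PR stages 3, 4 and 5 were weighed against nematode reads counted on tomato genes and against the 3 libraries with few low counts. From infected stage 3 to infected stage 5 their CPM had a median log2 ratio of -0.21, while the nematode share had a log2 ratio of 3.23, and 0 of the genes reached 0.8 of that, which argues against nematode reads. In a fit without the 3 libraries 214 of the 489 genes were called higher at all 3 stages, which argues against these libraries as the whole cause. Their effect on the size of the changes stays open: of 426 genes called with replicate 1, 84.3% kept at least 0.5 of their log2 fold change in replicate 2 at stages 4 and 5, and both replicates were set against the same uninfected libraries. A response of the host to infection stays among the possible explanations, as a hypothesis.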
